A study of Ascaris suum with 9 samples.

How the data were processed

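RNA sequencing measured transcript abundance in whole larvae of Ascaris suum, the large roundworm of pigs. The 9 libraries fall into 3 groups of 3 by the treatment in the labels: solvent control, biochanin A at 100 µM and red clover extract at 200 µg/mL, each for 3 hours. Per the labels' protocols, total RNA was isolated with TRIZOL, chloroform and isopropanol, and libraries followed a standard Illumina procedure. Strandedness is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

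The deposited table holds raw read counts per gene, 1 column per library, with no normalization by the authors; the values are whole numbers with a different total in each library. Its sheet name points to an Ascaris suum annotation labelled WBPS19. The aligner and the counting tool are not given in the sources used here, nor is the treatment of reads that match several genes. Counts of near-identical gene copies may therefore be split or dropped. DESeq2 is named without a role or version, per the submitters' processing notes. Columns were matched to samples through the library names in the sample descriptions, and 0 columns were left without a sample.

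The table pairs none of its 17974 gene identifiers with a gene name, and no reference annotation was used here. Identifiers are printed without the "gene:" prefix that all of them carry, and genomic positions were not analysed here. Gene lists for detoxification enzymes, transporters, stress proteins, ion channels, cuticle and other functions, and for markers of reproductive stages and RNA quality, had been fixed before the data were examined. They were defined by product names or protein sequences, so none of the lists was tested. By the rule for that case, also fixed beforehand, at most 2 identifiers that rose and 2 that fell are named per comparison: those with the largest fold change among genes with an adjusted p below 0.05, a mean of at least 5 CPM (counts scaled to library size) in at least 1 of the 2 groups, and no overlap between the libraries of the 2 groups.

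Genes were filtered with filterByExpr, which left 15177 of 17974; 626 genes had no read in any library. Counts were scaled with TMM and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) in one model over the 3 groups, with 6 residual degrees of freedom, robust dispersion and no block. P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Log2 CPM values, used for distances between libraries, had a prior count of 2. Nothing in the labels says whether the replicates came from separate batches of larvae, so p-values measure only the spread between these samples, which may be technical. The labels give no sequencing batch or date.

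Library totals ran from 44324212 to 53786882 counts, so 1 CPM before TMM scaling corresponds to 44.3 to 53.8 reads. The filter kept at least 99.985% of the counts of each library. Every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom of 17.1 to 124.1 over genes with at least 10 counts in the pair), so all 9 were counted as separate samples. The common dispersion corresponded to a coefficient of variation of 17.5% between libraries of one group.

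The workflow was tested on simulated data drawn from the means, library sizes and dispersions of the real libraries, with 200 genes changed in each treatment. For biochanin A against control, with 14998 genes tested, 57.1% of 1.5-fold, 69.6% of 2-fold and 77.0% of 4-fold changes were recovered, and 8.05% of the calls were false. For red clover extract against control the shares were 50.7%, 71.9% and 89.0%, with 4.11% false. Among genes of at least 5 CPM, 100% of the 4-fold changes were recovered in both comparisons. Far fewer genes were changed here than were called in the real data, and their directions were drawn at random. The shares therefore do not carry over to the real comparisons and do not test the scaling.

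The comparisons of the 2 treatments with control share the same 3 control libraries. Their overlap was set beside 20 simulations of unchanged groups against shared controls. The fold change covariance was also computed with disjoint controls, giving 1 control library to one treatment and the other 2 to the other. The 3 controls could not be split so that each part kept at least 2 libraries.

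Alternatives fixed beforehand were DESeq2 size factors within edgeR, DESeq2 1.42.0, limma voom (limma 3.58.1), no filter, a fit of only the 2 groups compared, a replicate block, a log2 fold change above 1, an adjusted p below 0.01, and leaving out each library in turn. Scaling by total counts only, removal of 9 covarying genes, abundance-dependent loess offsets and a restriction of the covariance to genes of at least 5 CPM were added after the data were seen.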

Results

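Transcript counts were obtained from 9 libraries of whole Ascaris suum larvae, 3 exposed to solvent, 3 to biochanin A and 3 to red clover extract for 3 hours. Biochanin A is a methylated isoflavone that red clover makes, so the design asks how the larvae respond to the plant extract and to one of its pure constituents. The control libraries held 45842836, 47119897 and 47142254 counts, the biochanin A libraries 53786882, 47069744 and 44324212, and the extract libraries 46236453, 50682988 and 50260353. Of 17974 genes, 15177 passed the filter and were tested. Spearman correlations of the raw counts were 0.986 to 0.994 within groups and 0.977 to 0.990 between groups. The first principal component of log2 CPM carried 30.5% of the variance and ordered the groups without overlap. Control libraries lay between -62.6 and -31.6 on it, extract libraries between 4.91 and 6.69, and biochanin A libraries between 34.8 and 45.4.

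Biochanin A changed 5341 of the 15177 genes after 3 hours, 35.2% of those tested. Of these, 2561 genes rose and 2780 fell relative to solvent control. Most changes were small: the median called rise was 1.42-fold and the median called fall was 1.42-fold. A change of over 2-fold was estimated for 520 of the genes that rose and 372 of those that fell, and one of over 4-fold for 129 and 68. The gene AgR009X_g116 rose most by the naming rule, from 2.67 ± 0.91 CPM in control to 35.7 ± 2.7 CPM (SD, n = 3 each), a log2 fold change of 3.74 ± 0.18 (SE). AgB04_g289, an abundant transcript, rose from 61.5 ± 6.1 to 640.4 ± 23.7 CPM, a log2 fold change of 3.38 ± 0.08. Among genes that fell, AgR001_g655 dropped from 18.4 ± 4.4 to 1.63 ± 0.51 CPM (log2 fold change -3.50 ± 0.24). AgR033_g018 dropped from 23.8 ± 4.4 to 2.11 ± 1.02 CPM (log2 fold change -3.48 ± 0.31). Adjusted p-values from edgeR's quasi-likelihood test were 4.0e-12 for AgR009X_g116, 1.5e-16 for AgB04_g289, 1.5e-09 for AgR001_g655 and 2.0e-07 for AgR033_g018. The balance of rises and falls depends on the scaling: with library totals in place of TMM, the log2 fold changes shifted by a median of -0.20, 1349 genes were called higher against 5188 lower, and 104 of the 5341 called genes changed sign.

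Red clover extract changed 2632 genes, 17.3% of those tested, of which 1418 rose and 1214 fell. The median called rise was 1.35-fold and the median called fall was 1.43-fold, and changes of over 2-fold were estimated for 231 genes that rose and 167 that fell. AgR009X_g116 again had the largest rise by the naming rule, to 21.3 ± 0.8 CPM against 2.67 ± 0.91 in control (7.99-fold, with an SE of 0.18 on the log2 scale, adjusted p = 1.5e-10 by edgeR's quasi-likelihood test). AgR030_g031 rose from 11.1 ± 0.9 to 61.7 ± 2.4 CPM (log2 fold change 2.48 ± 0.08, adjusted p = 5.3e-14), and reached 112.9 ± 4.5 CPM with biochanin A. AgR002_g419 fell from 8.09 ± 0.97 to 0.490 ± 0.069 CPM, which rests on 20 to 29 counts per extract library (log2 fold change -4.04 ± 0.45, adjusted p = 1.9e-06). AgR003_g168 fell from 22.2 ± 6.2 to 3.06 ± 0.60 CPM (log2 fold change -2.86 ± 0.22, adjusted p = 8.2e-09). With library totals in place of TMM the log2 fold changes shifted by a median of -0.15, and 744 genes were called higher against 2926 lower.

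**Figure D1:**
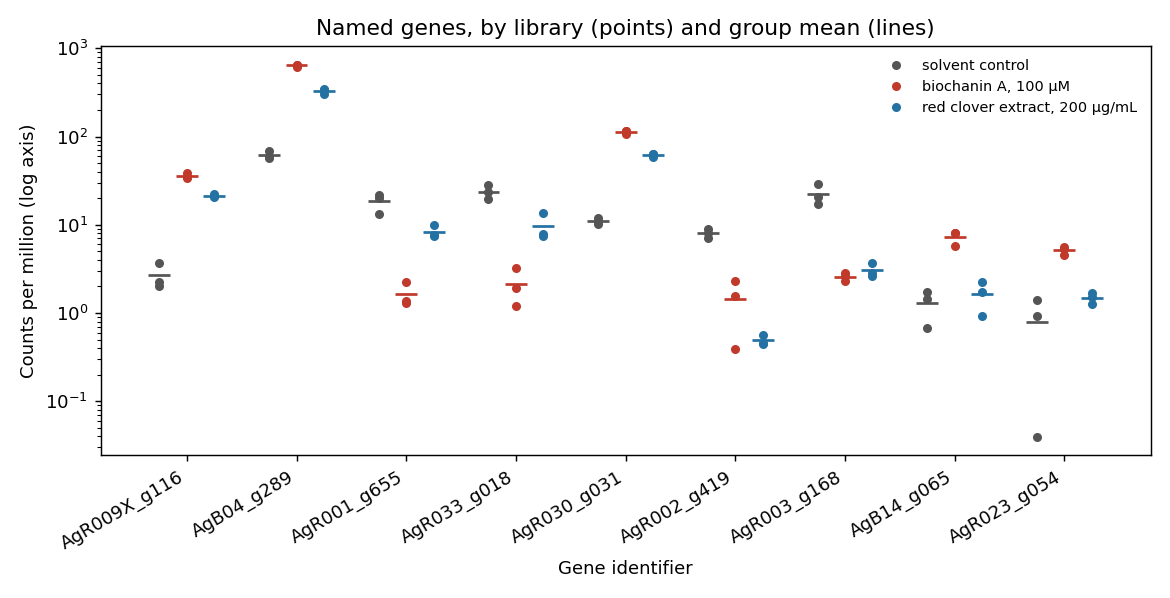
CPM values (TMM-scaled, log axis) of the 9 genes named in the 3 comparisons, with 1 point per library and a line at the mean of each group of 3. AgB04_g289 had group means of 61.5 CPM in control, 640.4 CPM with biochanin A and 328.6 CPM with extract, while AgR003_g168 lay at 2.58 and 3.06 CPM with the 2 treatments against 22.2 CPM in control.

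The 2 treatments changed many of the same genes in the same direction. Both raised 1229 genes and both lowered 862, a total of 2091 genes, which is 79.4% of the extract's calls and 39.2% of those of biochanin A. Independent lists of these lengths would share 239 higher and 222 lower genes, and 20 simulations of unchanged groups against shared controls gave at most 1 shared call. Those simulations called at most 2 genes in either comparison, so they do not show how much overlap shared controls add among 5341 and 2632 calls. Part of the excess may still come from the shared control libraries. With library totals in place of TMM, 612 genes were higher and 2434 lower with both. Opposite directions were called for 20 genes, 12 of them higher with biochanin A and lower with extract. Among the genes that both treatments raised, the median log2 fold change was 0.61 with biochanin A and 0.45 with extract. Among those that both lowered it was -0.62 and -0.54. Across all tested genes, which are not independent replicates, the fold changes of the 2 treatments correlated with a Pearson r of 0.69 and a Spearman rho of 0.68, against a mean Pearson r of 0.50 in the simulations. Their covariance was 0.294 against 0.072 in the simulations, a difference of 0.222. With disjoint control libraries it was 0.163 to 0.174 on log2 CPM values, against 0.261 with shared controls on that scale, and the Pearson r was 0.32 to 0.39 against 0.70. The covariance was 0.644 without control replicate 1, 0.494 without control replicate 2 and 0.352 to 0.406 without any other library. It was 0.731 without the filter on low counts. Restricted to the 10465 genes of at least 5 CPM, it was 0.136 against 0.009 in the simulations. On log2 CPM values of these genes it was 0.122 to 0.129 with disjoint controls, against 0.137 with shared controls.

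**Figure D2:**
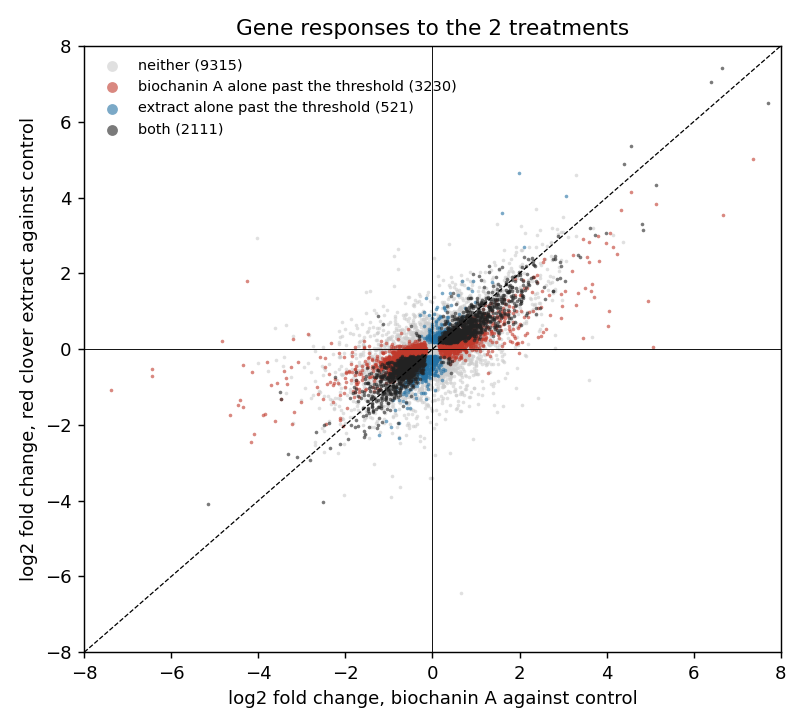
Log2 fold change against solvent control of each of the 15177 tested genes, with biochanin A on the horizontal and red clover extract on the vertical axis, coloured by which comparison passed an adjusted p of 0.05; the dashed line marks equal change. Of the 2111 genes called in both comparisons, 2091 have the same sign in both, 1477 of these with a smaller change with extract, and 20 have opposite signs.

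The direct comparison asked where extract and pure biochanin A differed at the doses used, 200 µg/mL and 100 µM. These doses are not matched, and how much biochanin A the extract contained is not given in the sources used here. The expression of 2239 genes differed, 1118 higher and 1121 lower with extract than with biochanin A, by a median of 1.32-fold and 1.34-fold. With library totals in place of TMM, 1615 were higher and 776 lower with extract. Of the 2091 genes that both treatments moved in the same direction, 1477 had a smaller fold change with extract, and for 479 of these the difference itself was called. A larger fold change with extract was estimated for 614, and called for 76. For the remaining 1536 of the 2091 genes the difference between the treatments was not called. For example, AgB04_g289 rose less with extract, at 328.6 ± 23.7 CPM, than with biochanin A (log2 difference -0.96 ± 0.07, adjusted p = 6.3e-08 by edgeR's quasi-likelihood test). AgR003_g168 differed by 0.25 ± 0.22 on the log2 scale, with an adjusted p of 0.52.

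Of the 3230 genes called with biochanin A and not with extract, 2903 (89.9%) had the same sign of change with both treatments. Among all tested genes this share was 76.8%. The shared control libraries favour equal signs: in the simulations of unchanged groups the mean share over all genes was 66.6%. No simulated share was computed for genes picked by their call with biochanin A. Of the 3230 genes, 1209 also differed between the treatments, 435 raised and 774 lowered by biochanin A. In the other direction, 228 of the 521 genes called with extract alone differed from biochanin A, 76 raised and 152 lowered by the extract. The direct comparison reuses the treated libraries that selected these genes, so it is not an independent check. The 2 named genes that were higher with extract are also the 2 named among those that biochanin A lowered. AgR001_g655 stood at 8.35 ± 1.40 CPM with extract, between control (18.4) and biochanin A (1.63), and differed from biochanin A by 2.36 ± 0.24 on the log2 scale (adjusted p = 3.0e-06 by edgeR's quasi-likelihood test). AgR033_g018 stood at 9.62 ± 3.46 CPM with extract and differed by 2.17 ± 0.30 (adjusted p = 0.00015). AgB14_g065 was raised by biochanin A to 7.25 ± 1.35 CPM, against 1.29 ± 0.54 in control and 1.63 ± 0.65 with extract, and was lower with extract than with biochanin A by a log2 difference of -2.15 ± 0.36 (adjusted p = 0.00046). AgR023_g054 was lower with extract (1.48 ± 0.21 CPM) than with biochanin A (5.18 ± 0.54 CPM), at an adjusted p of 0.046. That p was 0.080 to 0.13 without any 1 of the 6 treated libraries or control replicate 3, 0.13 with DESeq2 and 0.089 without the filter on low counts, and 0.00020 to 0.13 over all alternatives. The count of genes that differed was 1412 without biochanin A replicate 3 and to 1482 without extract replicate 2.

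In the treated libraries a larger share of the counts fell on the most abundant transcripts. The 100 most abundant genes of each library took 20.4 ± 0.5% of the counts in control, 25.4 ± 0.5% with biochanin A and 24.4 ± 2.0% with extract (mean ± SD, n = 3 each). Every treated library lay above every control library, and the exact two-sided permutation p was 0.1 for each treatment, the smallest that 3 libraries against 3 allow. A set of 9 genes that varied together between libraries of one group held 5.01%, 2.93% and 0.897% of the counts in extract replicates 1, 2 and 3, against 0.815% to 1.21% in control and 0.839% to 1.78% with biochanin A. With genes split into 5 equal classes by mean abundance, a split made after the data were seen, 1128 genes of the most abundant class rose with biochanin A and 508 fell. In the middle class 444 rose and 819 fell. The extract raised 713 and lowered 250 genes of the most abundant class, and raised 209 and lowered 363 of the middle class. Under scaling by library totals the most abundant class had 521 genes higher and 1244 lower with biochanin A, and 325 higher and 769 lower with extract, so the direction of this class depends on the scaling. With DESeq2 size factors it had 1180 higher and 468 lower with biochanin A, and 727 and 235 with extract. Its share of higher calls was still above that of the middle class under scaling by library totals, at 29.5% against 15.3% with biochanin A and 29.7% against 13.6% with extract. The mean abundance was taken over all libraries, treated ones included, so genes that rose could enter the most abundant class through the treated libraries. How much of these splits comes from that choice was not tested.

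**Figure D3:**
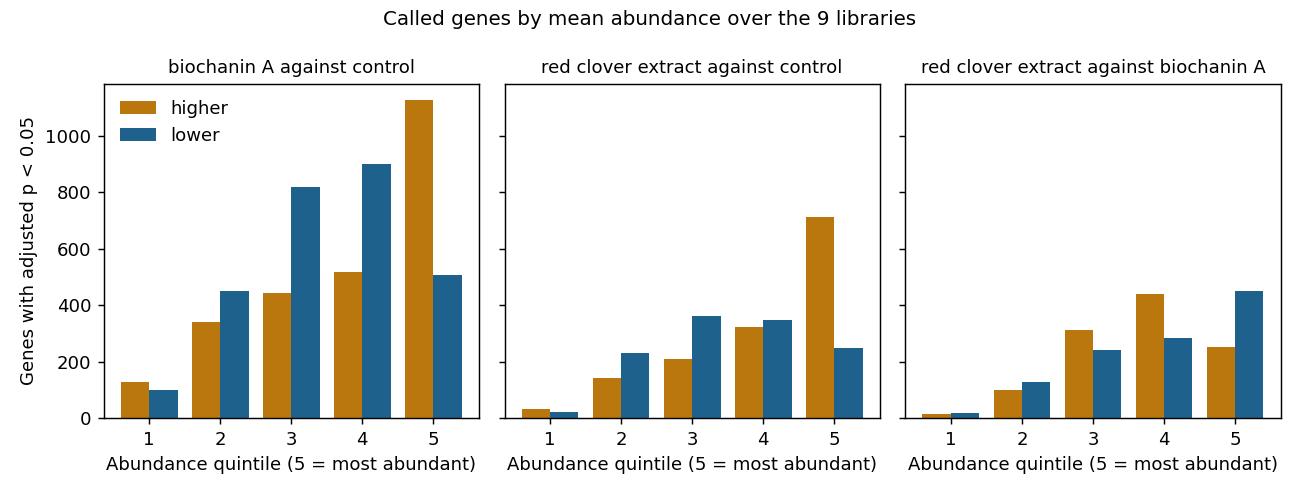
Number of genes with an adjusted p below 0.05 that were higher or lower in each of the 3 comparisons, by quintile of mean abundance over the 9 libraries (1 the least, 5 the most abundant). In the top quintile, 1128 genes rose and 508 fell with biochanin A, and 713 rose and 250 fell with red clover extract; scaled by library totals, more genes of this quintile were lower (1244 and 769) than higher (521 and 325).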

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

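The counts of called genes stayed within 1.5 times of the reported ones with DESeq2 size factors, DESeq2, limma voom, no filter, a fit of 2 groups, scaling by totals, loess offsets and without the 9 covarying genes. The last 3, and the covariance over genes of at least 5 CPM, were chosen after seeing the data. Similar counts do not mean the same genes. Under scaling by totals, without regard to direction, 4129 of the 5341 biochanin A calls and 1957 of the 2632 extract calls were made again. So were 1892 of the 2239 calls between the treatments and 1473 of the 2091 for both. With loess offsets these numbers were 4484, 2155, 1889 and 1654. With a replicate block, 5323 genes were called for biochanin A, 2620 for extract, 2201 between the treatments and 2107 for both, and no call of a named gene changed. Deviations from the group means of libraries with the same number correlated between -0.025 and 0.024. Not every library correlated best with its own number. Over all tested genes this gave no sign of a pairing by number, but it cannot exclude a shared batch. Requiring a log2 fold change above 1 left 892 genes for biochanin A, 398 for extract, 133 between the treatments and 288 for both, and an adjusted p below 0.01 left 1570 for extract, 1053 between the treatments and 1274 for both, by the construction of stricter thresholds. Leaving out 1 library gave 1412 (without biochanin A replicate 3) to 2573 (without control replicate 2) genes between the treatments, 4419 to 5574 for biochanin A, 1906 to 2781 for extract and 1555 to 2221 for both; between the treatments, 1482 genes were called without extract replicate 2. The fold change covariance was 0.731 with no filter, 0.315 with the replicate block and 0.136 over genes of at least 5 CPM. It was 0.352 to 0.644 without 1 library, the highest without control replicate 1. All of these leave-one-out values lay above the reported 0.294, also those without a treated library. The filter on low counts was applied anew in each of these fits, and the cause was not tested. Of the values of named genes under these alternatives, 229 kept their direction and their side of the threshold, and 11 kept only the direction, all of AgR023_g054 for extract against biochanin A. Its adjusted p was 0.13 with DESeq2, 0.089 with no filter, 0.051 with loess offsets and 0.00084 to 0.13 without 1 library, and the reported 0.046 does not pass 0.01. Part of the 229 was set in advance. Named genes were picked for large changes, so the limit on the log2 fold change could not remove them. Some of the libraries left out were also not among those compared. The planned tests of gene lists were not run, since the identifiers have no names here. At 44324212 to 53786882 counts per library, depth limits genes of low abundance most: in simulated data, 77.0% of 4-fold changes with biochanin A were recovered over all genes and 100% over genes of at least 5 CPM.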

Other observations

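The slope test of the 9 covarying genes, the test without the 100 most abundant genes, the test of reads counted for both of 2 consecutive genes, the comparison of identifier classes with matched lists and the permutations of consecutive identifiers were chosen after the results were seen, and all 3 weighed patterns were noticed in the same data on which they were tested. The genes AgR002_g269 to AgR002_g272, AgE51_g005 and AgR047_g055 were chosen after their values were seen. What the letters of an identifier stand for is not given in the sources used here, so identifier classes are described only as such. Of 260 tested genes with an identifier beginning AgE, 15 rose and 5 fell with biochanin A. Lists matched on abundance held 34.5 called genes on average, and 0.11% of 10000 such lists held fewer than the observed 20. The ranges of matched lists given here leave out the most extreme lists at both ends, so some lists lay outside them. The lists drew genes one by one, while genes with consecutive identifiers changed together, as described below. The ranges may therefore be too narrow and the percentiles too extreme. They were also read over all identifier classes and comparisons without correction. With extract the 9 called AgE genes lay within the range of matched lists (7 to 19). Between the treatments the 3 called lay below it (4 to 14), at percentile 0.64 of the 10000 lists. Genes with identifiers of the form AgR009X_g116, with an X after the first number, were called less often than the mean of matched lists in each comparison: 743 against 793.9 with biochanin A, 350 against 403.5 with extract, and 300 against 340.2 between the treatments. Without matching, the shares called in this class were 35.9%, 16.9% and 14.5%, against 35.2%, 17.3% and 14.8% over all tested genes. Genes with an X after AgB and the first number lay within the range of matched lists in each (301 in 269 to 317, 139 in 127 to 167, and 106 in 105 to 143); the difference between these 2 classes was not tested. Genes with AgR and no X lay above the range of matched lists with extract (1429, range 1320 to 1406), at percentile 99.88 of the lists. They lay within the range in the other comparisons (2804 in 2724 to 2831, and 1201 in 1119 to 1202).

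Genes with consecutive identifiers changed together: among 6235 pairs with both genes at a mean of at least 8 CPM, the biochanin A fold changes of the 2 genes correlated with a Spearman rho of 0.28 across pairs, above the highest of 1000 permutations within identifier prefixes (0.037). Noise shared by consecutive genes within groups accounted for 4.27% of the covariance of the fold changes, which argues against such noise as the whole cause. A test set down beforehand took a higher rho in pairs within 2-fold in abundance (0.39, 2722 pairs) than in pairs over 16-fold apart (-0.04, 250 pairs; 95% bootstrap interval of the difference 0.29 to 0.56) as evidence against reads counted for both genes, but such reads would make the counts of the pair alike, so this decides nothing. Reads counted for both genes would carry their library noise as well, and the correlation of the within-group deviations (0.177) was 60.8% of that of the fold changes (0.291; 95% bootstrap interval of the percentage 51.6 to 71.7), between the bounds set for and against this, so it stays open. Genes transcribed together, local duplicates or 1 gene annotated as several models may also account for it and were not tested here, since positions and sequences were not analysed.

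The rise of abundant relative to less abundant genes was seen in each biochanin A library: the median log2 CPM of the top quintile minus that of the third was higher in every biochanin A library than in every control library, with a gap of 0.135 between the groups against a largest range of 0.069 within any group. The quintiles were set by the mean over all libraries, treated ones included. Genes that rose could therefore enter the top quintile through the treated libraries, and how much of the gap this makes was not tested. The gap argues against a trend that varies from library to library only as far as it does not come from this choice. A few abundant genes taking counts from all others alike would shift both quintiles alike, since the difference between quintiles does not depend on a library's scaling factor. Such a loss alone would leave no gap, so the gap of 0.135 argues against it, with the same limit. Without the 100 most abundant genes the gap was 0.129 against a largest range of 0.068 within any group. This adds little to the first gap, since removing 100 genes could hardly move the median of a quintile of 3036 genes. The split of the called genes of the top quintile without those 100 (1086 higher, 471 lower), a test set down beforehand, decides nothing here, since it depends on the scaling and TMM trims extreme genes. A response of the larvae and a difference in RNA handling between the groups stay open as hypotheses, and neither was tested.

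A set of 9 genes, found by clustering 42 abundant genes with a high variance within groups, varied together between libraries of the same group and includes AgR002_g269 (8702 CPM on average, 3558 to 25696 CPM over the libraries). AgR002_g270, AgR002_g271 and AgR002_g272, with the next identifiers, were in the set too, at 6766, 1478 and 467 CPM on average. The remaining genes of the set had means of at most 189 CPM. Whether the genes with consecutive identifiers share reads was not tested. The lowest correlation between the within-group deviations of any 2 of the 9 was 0.914. The clustering used the same correlations, so a high value was partly set by the choice of genes. The adjusted p-values of the 9 genes by edgeR's quasi-likelihood test were at least 0.065 with biochanin A, 0.10 with extract and 0.27 between the treatments. A single RNA source that differs in amount between libraries, with no other transcripts of these genes, would give each gene a slope near 1 on the mean of the other 8. The slopes of 2 genes, AgE51_g005 (0.51 ± 0.04, SE) and AgR047_g055 (0.50 ± 0.05), lay below 0.75 by more than 2 standard errors, which argues against that simplest form; a shared source on top of a constant level in these 2 genes, such as abundant RNA removed to different degrees, stays open, and no biological explanation was tested. 

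The 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split was 1 of 10 in each comparison, with 5341, 2632 and 2239 genes, and the highest of the other splits had 0 by edgeR's quasi-likelihood test. Each other split mixes libraries of both groups, so a difference between the groups adds to the spread within each side. The 0 calls therefore do not show how many genes chance alone would give. At an unadjusted p under 0.05 the other splits had at most 616 genes for biochanin A against control, 1224 for extract against control and 599 between the treatments.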
